A study of Mus musculus with 2 samples.

How the data were processed

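RNA was sequenced from 2 cultures of mouse T helper cells, 1 per group. Per the labels, naive CD4+ CD62L+ T cells came from spleen and lymph nodes of C57BL/6 mice 8 to 12 weeks old. They were stimulated for 3 to 4 days with anti-CD3 bound to the plate (1 µg/ml) and anti-CD28 (1 µg/ml), and IL-6, IL-1 and IL-23 (20 ng/ml each) were added to drive them to the Th17 fate. The activin-A culture also received activin-A, a cytokine of the TGF-β family, at 100 ng/ml, and the control culture received its vehicle, PBS. Per the labels' protocols, libraries were made with a kit that captures poly(A) RNA and keeps no record of the strand.

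The submitters' processing notes name CASAVA 1.8, cutadapt, TopHat2, SAMtools, bedtools and the mouse genome build mm9. The role of each tool, the annotation release and the program that normalized the counts are not given in the sources used here. The authors deposited 1 table of 37583 gene rows, each with a normalized read count per library, a score written in whole numbers. The deposited table also gives the GC content of each gene as a fraction, its coordinates, strand, name and class. Coordinates are printed as the table gives them, in mm9, counted from 1; the length of 98.5% of 2278 small RNA rows matched the GENCODE M21 length of the same identifier when counted that way. Gene names are those of the table, and coordinates of another build served only for that length check.

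The whole numbers are not raw counts. In the control column 57 of the 399 lowest whole numbers never occurred, with a median spacing of 7, and activin-A values at a regular spacing were 2.03 times as frequent as their neighbors. Such gaps and pile-ups are left when counts are divided by a factor per library and rounded. A search over factors gave 1.17 units per control read and 0.875 units per activin-A read, that is, size factors of 0.858 and 1.14. With a rounding tolerance of 0.5, 99.9% of control values under 3000 matched a whole number of reads, where multiples of that size reach 85.8% of all whole numbers by construction. The recovered depths were 47024732 reads in the control library and 71666565 in the activin-A library. These reads served for counting intervals alone. No count model was fitted, because the deposited unit is normalized and each group has 1 library.

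Ratios were computed here as log2 of the activin-A value plus a pseudocount of 1 over the control value plus 1, on the deposited scaling, and folds are those ratios on the linear scale, which understates the fold of low genes. Genes entered the counts and the lists when their mean over both libraries was at least 50, and were counted as higher or lower at 2-fold or more. Counting intervals are exact conditional binomial intervals at 95% of the ratio of the recovered reads. They cover counting error only and compare these 2 libraries, not the conditions. With 1 library per group no test between conditions, standard error or p-value was computed, and no difference has a replicate check.

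Before the data were examined, 35 gene lists were fixed. They cover the Th17 core, pathogenic Th17, non-pathogenic Th17, the ectonucleotidase and adenosine pathway, hypoxia and HIF1 targets, glycolysis, oxidative phosphorylation, and the activin and TGF-β pathway. Further T cell lists cover regulatory and co-inhibitory genes, aryl hydrocarbon receptor targets, Th1, Th2, Tfh, cytokine receptors, and chemokines with their receptors. Response lists cover interferon-stimulated genes, cell cycle, cholesterol synthesis, amino acid response and ATF4 targets, unfolded protein response, immediate early, naive and memory T cell, p53 and apoptosis, and heat shock. Marker lists cover pan T cells, CD8 T and NK cells, B cells, myeloid cells, innate-like T cells, erythroid cells and platelets, and stromal and endothelial cells. Control lists cover ribosomal proteins, mitochondrially encoded genes, replication-dependent histones and housekeeping genes. Of 551 list entries, 537 were in the table. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was set apart when its percentile lay under 2.5 or over 97.5, and lists with under 3 members past the floor have values only. Percentiles describe these libraries and test no condition.

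Genes are named by a rule fixed at the same time: 24 focus genes of the study's subject, the 12 highest and 12 lowest genes with a mean of at least 100, up to 4 members per list with the largest ratio in either direction, and marker genes of other cell types. The highest and lowest genes leave out predicted Gm and Rik genes, receptor segments and small RNA genes. Some genes that the rule takes are not reported here. Genes named outside that rule are marked as chosen after their values were seen.

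The steps were tested on simulated counts drawn for the real genes and depths. Across 12377 simulated genes past the floor, the 2-fold rule took 40 of 40 genes set to 2.5-fold and 0 of 40 set to 1.5-fold, and it took 0 of 12184 unchanged genes. These simulations held counting error only and no variation between cultures, so they give no rate of false calls between conditions. Counting intervals held the true fold for 95.1% of genes, and 5.0% of 200 unchanged lists of 15 genes fell outside the percentile limits. Alternatives changed the pseudocount, the floor, the scaling between libraries, the fold threshold, the genes entering and the random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

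Rows that overlap other rows need care. The table holds 6726 rows that lie wholly inside another row, 1297 of them protein-coding, and 0 of the 6726 are above 0, whereas 23.1% of the 14456 protein-coding rows untouched by another row are at 0. A gene listed at 0 inside another row was therefore read as not measured. Of protein-coding rows past the floor, 39.0% overlap another row in part. No mitochondrial rows were analysed here.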

Results

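The data were 1 RNA-seq library of mouse Th17 cells cultured with activin-A and 1 library of control Th17 cells cultured with PBS, so no difference below has a replicate check. Th17 cells are T helper cells that secrete IL-17 and can drive autoimmune inflammation. Normalized counts summed to 54817708 in the control library and 62722491 in the activin-A library, from 47024732 and 71666565 recovered reads. Of 37583 gene rows, 12516 had a mean of at least 50, and 11827 of these were protein-coding. The comparison asked how activin-A alters the Th17 program, in particular its pathogenic arm, the ectonucleotidases CD39 and CD73, and Hif1a. Intervals are 95% counting intervals, which cover counting error only, and each percentile places a list among 10000 matched random lists as a description of these libraries. Scaling both libraries to the same total, an alternative to the deposited scaling, shifted every log2 ratio by −0.19 and left percentiles as they were. The total counts every row, and the larger activin-A share of the 30 abundant genes given below produces that shift. Without those genes the activin-A total would not be the larger one. The trimmed mean of M-values, another scaling that leaves out the rows with the most extreme ratios, shifted every log2 ratio by −0.018. The libraries also differed in RNA composition, beside every gene group described here: small noncoding RNA took 0.0407% of the control total and 0.734% of the activin-A total, and 30 abundant genes that were at least 4-fold higher took 3.43% and 19.04%.

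Genes that define the Th17 lineage were higher in the activin-A library. Il17f (chromosome 1, 20767232 to 20774351, mm9) stood at a normalized count of 2263 in control and 9183 with activin-A, 4.06-fold higher (interval 3.87 to 4.26), and Il17a stood at 1536 and 2826, 1.84-fold higher (1.72 to 1.96). The chemokine receptor Ccr6 was 3.93-fold higher (3.32 to 4.70) and its ligand Ccl20 3.21-fold higher (2.66 to 3.95). Of the 15 members of the Th17 core list, 7 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.29 at percentile 100, or 0.09 under scaling to the same total, in a library whose histone list median was 1.16. Il23r was 1.22-fold higher (1.14 to 1.31) and Rora 1.12-fold higher (1.07 to 1.18), a direction that turned when both libraries were scaled to the same total. Il22 stood at 317 and 714, 2.25-fold higher (1.96 to 2.59), and is uncertain because the near-identical copy Iltifb, at 191 and 406 and chosen after its values were seen, can share its reads. Members that were lower included Batf, 1.40-fold lower (1.36 to 1.45), Il21, 1.22-fold lower (1.20 to 1.24), Irf4, 1.14-fold lower (1.13 to 1.15), and Stat3, 1.05-fold lower (1.03 to 1.07).

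The list of genes linked to pathogenic Th17 cells was set apart as lower by its median, but its members went in both directions. Its median log2 ratio was −0.15 at percentile 1.39 and its mean −0.03. Of 17 members, 2 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 13 within 1.5-fold. At 2-fold, 2 members were higher and 0 lower. Glycolysis genes, not set apart, also had a median of −0.15. Tbx21, which encodes the Th1 factor T-bet, stood at 2946 and 1966, a log2 ratio of −0.58. The checkpoint receptor Lag3 was 1.57-fold lower (1.53 to 1.62). Csf2, which encodes the cytokine GM-CSF, stood at 204 and 134, 1.52-fold lower (1.22 to 1.91), but other rows covered 86.3% of its row, so its value rests on the remainder. The higher members were Il22, 2.25-fold higher (1.96 to 2.59) and uncertain as stated above, and Il3, 2.16-fold higher (1.43 to 3.39). Ifng stood at 336 and 324, and its interval (0.825 to 1.13 for activin-A over control) included no difference.

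The non-pathogenic Th17 list was not set apart, with a median of 0.19 at percentile 95.6, which turned to −0.0061 under scaling to the same total and to −0.0072 at percentile 37.6 with a floor of 200. Among its 8 members, Ahr was 2.23-fold higher (2.02 to 2.48), Il1rn, the antagonist of the IL-1 receptor, 1.44-fold higher (1.27 to 1.63), and Maf 1.41-fold higher (1.35 to 1.48). Il10, an anti-inflammatory cytokine gene, stood at 445 and 317, 1.40-fold lower (1.21 to 1.63). The list of aryl hydrocarbon receptor targets had a median of 1.16 at percentile 99.99, over the 4 of its 7 members past the floor. That median lies between Ahr, the receptor gene itself, at a log2 ratio of 1.16 and Il22, called uncertain above, at 1.17. It therefore does not show that targets of the receptor were higher as a group. Ahrr, the repressor of that receptor, stood at 37 and 103, 2.74-fold higher (1.86 to 4.23), beside Ahr and Il22. Tiparp was 1.09-fold higher (1.02 to 1.16), a direction that turned under scaling to the same total. The list members under the floor, named after their values were seen, were also higher on few reads. Cyp1a1 stood at 3 and 19 (interval 1.65 to 28.7) and Nqo1 at 30 and 54 (1.12 to 2.95). Cyp1b1 stood at 1 and 7, and its interval (0.805 to 267) included no difference.

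Of the genes for the ectonucleotidases CD39 and CD73, the CD73 gene differed far more in RNA. Nt5e, the CD73 gene (chromosome 9, 88222447 to 88266927), stood at 473 and 1592, 3.36-fold higher (3.02 to 3.75) with activin-A. Entpd1, the CD39 gene (chromosome 19, 40686856 to 40816092), stood at 403 and 478, 1.19-fold higher (1.03 to 1.36). Its log2 ratio of 0.25 is little larger than the shift of −0.19 under scaling to the same total, where its interval includes no difference. The trimmed mean of M-values shifted it by −0.018 only. The ectonucleotidase and adenosine list had a median of 0.20 at percentile 99.8, or 0.0024 under scaling to the same total, and Nt5e was the 1 member of 15 at least 1.5-fold higher, with the other 14 within 1.5-fold. The ATP receptor gene P2rx7 was 1.45-fold higher (1.30 to 1.63), Cd38 1.45-fold higher (1.27 to 1.65) and Dpp4 1.39-fold higher (1.31 to 1.48), with 67.1% of the Dpp4 row overlapped.

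**Figure D1:**
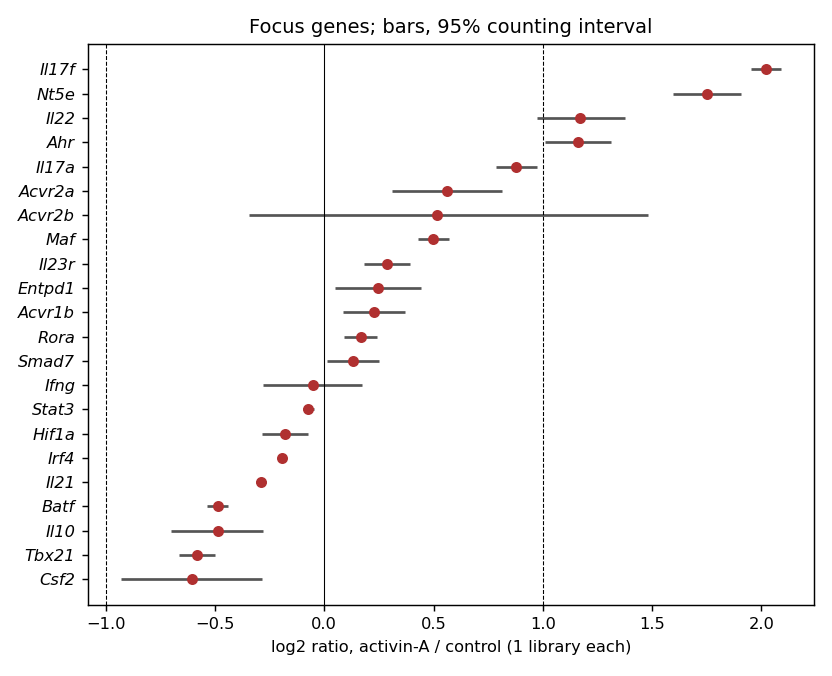
Log2 ratio of the activin-A over the control library (x axis) for focus genes named in advance, above 0 and reported here (y axis), 1 library per group. Points are ratios with a pseudocount of 1, bars are 95% counting intervals of recovered reads, and dashed lines mark 2-fold; Il17f at 2.02 and Nt5e at 1.75 lie highest and Csf2 at −0.60 lowest.

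Hif1a and its targets differed little between the libraries. Hif1a (chromosome 12, 75002362 to 75048517), which encodes the oxygen-regulated factor HIF-1α, stood at 1581 and 1398, 1.13-fold lower (1.05 to 1.22), with 45.6% of its row overlapped. These are RNA values, and HIF-1α protein was not measured here. The hypoxia and HIF1 list had a median of 0.01 at percentile 98.5, with 12 of 24 members above 0 and 12 below, and its sign turned under 2 other scalings, after removal of the GC trend, and with no floor, where it was no longer set apart (percentile 95.5). Adm, which encodes adrenomedullin, was the 1 member at least 1.5-fold higher, with a log2 ratio of 0.68, and Pfkfb3 was 1.27-fold lower (1.23 to 1.32). Pfkfb4 stood at 584 and 697 and Egln1, an oxygen sensor, at 17335 and 14816. Of the 18 glycolysis genes, 17 were below 0 and all 18 lay within 1.5-fold, with a median of −0.15 at percentile 7.16, not set apart. Hk2, the hexokinase of activated T cells, was 1.24-fold lower (1.21 to 1.27). Hk1, with 20.8% of its row overlapped, Pfkm and Gapdh had log2 ratios of −0.26, −0.26 and −0.23. Oxidative phosphorylation genes had a median of −0.06 at percentile 56.2, and Cycs, Sdha, Atp5a1 and Atp5g1 had log2 ratios of −0.21, −0.19, −0.17 and −0.17.

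The activin and TGF-β pathway list was not set apart, with a median of −0.04 at percentile 38.1 and 21 of 22 members within 1.5-fold. The receptor gene Acvr2a was 1.47-fold higher (1.24 to 1.76), and Acvr1b 1.17-fold higher (1.06 to 1.29). Acvr2b stood at 20 and 29, under the floor, with an interval of 0.789 to 2.79. Bambi, a pseudoreceptor that dampens TGF-β signaling, stood at 56 and 90, a log2 ratio of 0.67. Inhba, which encodes the subunit of activin-A itself, was 1.38-fold lower (1.32 to 1.46). Smad7, the inhibitory Smad, stood at 1095 and 1199, and this direction turned when the libraries were scaled to the same total.

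The regulatory and co-inhibitory list was not set apart, with a median of −0.08 at percentile 28.7. Of its 18 members past the floor, 2 were at least 1.5-fold higher, namely Ikzf2 at 2.39-fold (1.84 to 3.17) and Ctla4 at 1.54-fold (1.51 to 1.57), and 2 were at least 1.5-fold lower, namely Tigit at 1.69-fold, with counts of 2597 and 1539, and Lag3. Foxp3, the regulatory T cell factor, was listed at 0 in both libraries, but its row lies inside that of Ppp1r3f, and 0 of the 6726 rows that lie inside another row were above 0. Its expression was therefore not measured.

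Th2 genes formed the T helper list with the lowest median. It was −0.58 at percentile 0, with 4 of 9 members at least 1.5-fold lower and 0 at least 1.5-fold higher. The Th2 cytokine gene Il13 stood at 10450 and 3268, 3.20-fold lower (3.08 to 3.32), and Il5 stood at 407 and 108, 3.74-fold lower (3.07 to 4.68), with 15.4% of its row overlapped. Gata3, the Th2 lineage factor, stood at 8471 and 3660, 2.31-fold lower (2.23 to 2.40), with 30.05% of its row overlapped. The chemokine receptor Ccr8 was 1.85-fold lower (1.76 to 1.94). The activin-A library that gave these values also held more small noncoding RNA, at 0.734% of its total against 0.0407% in control.

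Th1 genes were higher by list median, at 0.18 and percentile 99.8, although Tbx21 was lower. The IL-18 receptor genes Il18r1 and Il18rap were 3.33-fold (2.99 to 3.72) and 2.06-fold higher (1.79 to 2.37), and the transcription factor gene Hlx 1.73-fold higher (1.46 to 2.06). Cytokine receptors had a median of 0.07 at percentile 99.2, with Ifngr1 1.52-fold higher (1.43 to 1.61), Il1r1 1.51-fold higher (1.27 to 1.79) and Il10ra 1.33-fold lower (1.27 to 1.39). Both medians turned negative under scaling to the same total. The Tfh list was not set apart, with a median of −0.03 at percentile 38.7 and a mean of 0.04. Sh2d1a, which encodes the adaptor SAP, was 1.70-fold higher (1.59 to 1.83), Cxcr5 1.53-fold lower (1.26 to 1.88), Tox2 1.36-fold higher (1.04 to 1.79) and Icos 1.30-fold higher (1.27 to 1.33). Chemokines and their receptors had a median of 0.03 at percentile 65.9, which turned negative under scaling to the same total or with no floor, with Ccr6 and Ccl20 at one end and Ccl22, 2.81-fold lower (2.47 to 3.21), at the other.

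**Figure D2:**
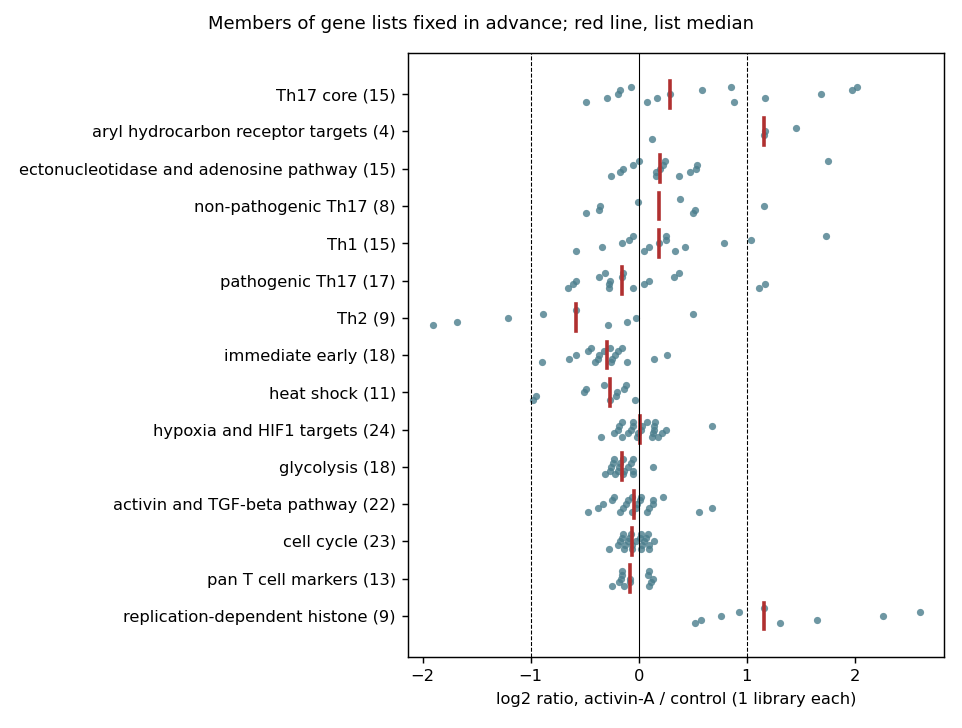
Log2 ratio of the activin-A over the control library (x axis) for members past the floor of 15 of the gene lists (y axis, number of members in brackets), 1 library per group. Each point is a gene and each red line a list median, and dashed lines mark 2-fold; the Th17 core median of 0.29 lies above 0 and the Th2 median of −0.58 below it.

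Genes induced early by T cell receptor signals were lower. The immediate early list had a median of −0.29 at percentile 0, with 16 of 18 members below 0 and 2 at least 1.5-fold lower, in the same library with the higher small noncoding RNA share (0.734% against 0.0407%). Egr2 was 1.86-fold lower (1.78 to 1.94), Egr1 1.56-fold lower (1.51 to 1.61) and Jund 1.39-fold lower (1.34 to 1.43), with 18.9% of the Jund row overlapped, and Egr3 had a log2 ratio of −0.58. Heat shock genes had a median of −0.26 at percentile 0.07, and 11 of 11 members were below 0. Hspa1b stood at 5278 and 2741, 1.93-fold lower (1.84 to 2.02), and Hspa1a at 147 and 74. Both are uncertain, being near-identical copies that can share reads, and 75.6% of the Hspa1a row is overlapped. Hsph1 was 1.42-fold lower (1.38 to 1.46) and Bag3 1.40-fold lower (1.29 to 1.53).

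In the remaining response lists most members lay within 1.5-fold. Cell cycle genes had a median of −0.06 at percentile 57.7 with 23 of 23 members within 1.5-fold, and Mki67 was 1.21-fold lower (1.18 to 1.23), with Mcm3, Plk1 and Cdc20 at log2 ratios of −0.19, −0.17 and −0.15. Cholesterol synthesis genes had a median of −0.11 at percentile 25.1, and Srebf2 and Fdft1 had log2 ratios of −0.31 and −0.26. The unfolded protein response had a median of −0.11 at percentile 35.5, with Creld2, Canx, Calr and Hsp90b1 at −0.28, −0.23, −0.22 and −0.19. Amino acid response and ATF4 targets had a median of 0.02 at percentile 98.2, set apart as higher, a mean of −0.01 and 17 of 17 members within 1.5-fold, and the median turned negative under scaling to the same total. In that list Sesn2, with 33.0% of its row overlapped, Atf3, Trib3 and Slc7a11 had log2 ratios of −0.37, −0.30, 0.25 and −0.16. Interferon-stimulated genes had a median of −0.01 at percentile 35.4, which turned positive with no floor or a floor of 200, with Oas1a 1.93-fold lower (1.51 to 2.49), Ifi44 1.70-fold lower (1.34 to 2.19), Gbp3 1.49-fold higher (1.37 to 1.62) and Ifit1 1.38-fold higher (1.04 to 1.84). The p53 and apoptosis list had a median of −0.01 at percentile 92.6 and a mean of 0.01, with Fas, Zmat3, Bcl2l1 and Bcl2 at 0.37, −0.34, −0.31 and 0.31. Naive and memory T cell genes had a median of −0.12 at percentile 16, with Klf3 1.52-fold lower (1.27 to 1.81), S1pr1 and Il7r at 0.45 and 0.33, and Bach2 at −0.32.

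Markers of other cells gave no list set apart. Pan T cell markers had a median of −0.08 at percentile 70.1, with Zap70, Cd3e, Cd247 and Cd28 at log2 ratios of −0.24, −0.18, −0.16 and −0.16. The CD8 T and NK list had a median of −0.06 at percentile 11.4 and a mean of 0.12, since Klrd1 was 2.19-fold (1.85 to 2.62) and Klrk1 2.02-fold higher (1.76 to 2.33), whereas Prf1, which encodes perforin, was 1.41-fold (1.28 to 1.56) and Nkg7 1.31-fold lower (1.26 to 1.37). B cell markers had a median of −0.13 at percentile 2.91, just inside the limit, and passed it with no floor or a floor of 200, but not among protein-coding genes alone (−0.0018 at percentile 34.6). Igkc stood at 1029 and 682, Cd79a at 324 and 236, Cd79b at 374 and 278, and Cd74 at 11430 and 9391. The myeloid list had a median of −0.07 at percentile 24.6 and a mean of 0.12 over 3 members, with Itgam at 107 and 157, Cd68 at 183 and 167, and Cst3 at 3777 and 3600. Innate-like T cell markers had a median of −0.04 at percentile 38.1 over 3 members, which turned positive with no floor, with Il2rb, Blk and Zbtb16 at −0.26, 0.17 and −0.04, and the sign for Blk turned under scaling to the same total. Stromal and endothelial markers had a median of 0.13 at percentile 60.0 and a mean of −0.13 over 3 members, and the median turned negative under scaling to the same total, with Dcn at 136 and 81, Pecam1 at 1283 and 1492, and Kdr at 106 and 116, the last turning under scaling to the same total. Of the erythroid and platelet list only Car2 passed the floor, at 230 and 177. The mitochondrially encoded list had 0 members in the table.

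Ribosomal protein genes had a median of −0.14 at percentile 13.2, with Rps2, Rps4x and Rpl4 at log2 ratios of −0.30, −0.21 and −0.21. Housekeeping genes had a median of −0.12 at percentile 23.2, with Actb, Gapdh and Sdha at −0.24, −0.23 and −0.19. Of 33 lists with a percentile, 8 were set apart as higher and 4 as lower, where lists of unrelated genes would give 1.65. The fixed lists share members and hold related genes, so these numbers do not measure an excess over chance. Against random lists not matched on expression, hypoxia, cytokine receptor and amino acid response genes were no longer set apart, and glycolysis and ribosomal protein genes became so.

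Across all genes, 301 were at least 2-fold higher in the activin-A library and 74 at least 2-fold lower, while 97.0% lay within 2-fold. Scaling to the same total gave 219 higher and 122 lower, and under it Ahr, Il22, Il3, Il18rap, Klrd1 and Klrk1 were no longer 2-fold higher. The higher genes included many transcripts that lack a poly(A) tail. Small noncoding RNA rows accounted for 58 of them, out of 60 past the floor, with a median log2 ratio of 6.21. Of 53 histone rows, 38 were at least 2-fold higher, and the replication-dependent histone list fixed in advance had a median of 1.16 at percentile 100, with Hist1h1b, Hist1h4d, Hist1h3a and Hist1h2bc at 2.60, 2.26, 1.65 and 1.31. Histone genes are near-identical copies, so their single values are uncertain. Among protein-coding genes other than histones, 164 were at least 2-fold higher and 71 lower.

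**Figure D3:**
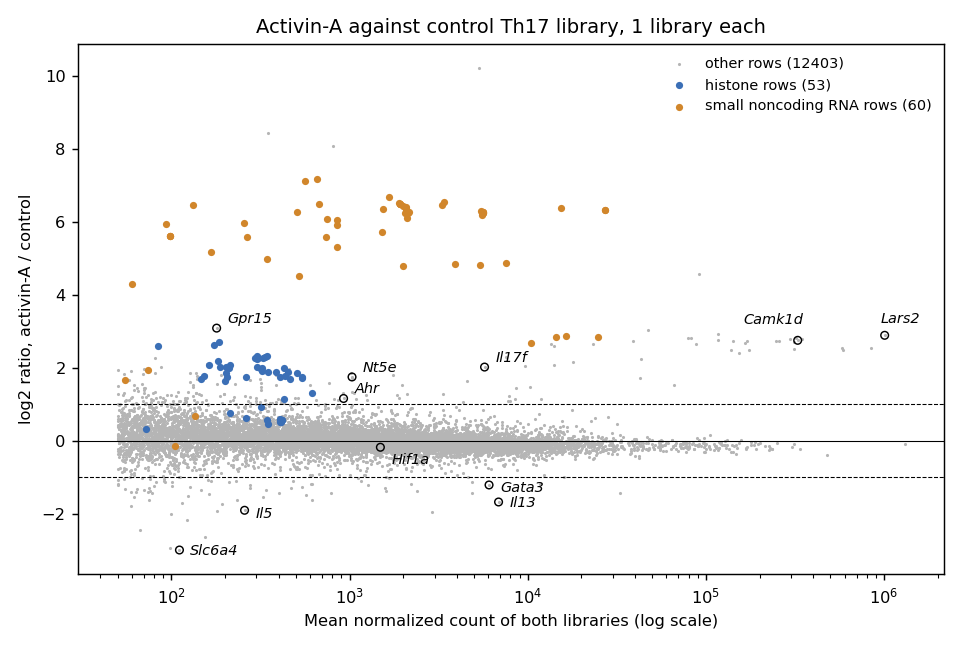
Log2 ratio of the activin-A over the control library (y axis) against the mean normalized count (x axis, log scale) for the 12516 gene rows with a mean of at least 50, 1 library per group. Dashed lines mark 2-fold; small noncoding RNA rows (orange, median 6.21) and histone rows (blue, median 1.78) lie above most other rows, and labelled circles are named genes.

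The highest named genes were mostly abundant in both libraries. Lars2, a mitochondrial leucyl-tRNA synthetase gene, stood at 239433 and 1775212, rank 1 with activin-A, and Il31ra, an IL-31 receptor gene, at 79266 and 557993. AY036118, classed as a pseudogene, stood at 7442 and 176085, a log2 ratio of 4.56. Cntnap5b, Col6a6, Lars2, Il31ra, Zc3h7a, Trpm3, Camk1d, Vwa3a, Rsph3a and Tmem56 lay between 3.03 and 2.74. Rsph3a has a near-identical copy and is uncertain. Besides Il17f, 30 protein-coding genes with a control value of at least 2000 were at least 4-fold higher, in a range of 4.14-fold to 8.19-fold. Reads of repeated sequence inside these gene bodies may be counted for them, so their values need not reflect expression of the named genes. Outside that group, Gpr15, a homing receptor gene of the large intestine, stood at 37 and 322, 8.50-fold higher (6.01 to 12.8).

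The 12 lowest named genes included Th2 cytokine genes and genes of diverse function. Slc6a4, the serotonin transporter gene, stood at 198 and 24, 7.96-fold lower (5.57 to 13.1), and Fa2h, a fatty acid hydroxylase gene, at 268 and 42, 6.26-fold lower (4.66 to 8.90). Layn was 4.49-fold lower (3.33 to 6.41), Dgkk 3.86-fold lower (3.63 to 4.11) and the growth factor gene Hgf 3.83-fold lower (2.99 to 4.97). Il5, Osr2, Fcrls, Il13, Dpysl3, Adamtsl3 and Prss2 had log2 ratios from −1.90 to −1.54, and Prss2 belongs to a family of trypsinogen copies that can share reads.

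Some genes that T cells use were listed at 0, and their rows lie inside other rows; those named here were chosen after their values were seen. B2m lies inside Patl2, Cd27 inside Vamp1, Il2rg inside Gm20489 and Tnfrsf18 inside Gm16008. Rpl13, Cox4i1 and Slc7a5 lie inside Gm20388, a row of 4.43 Mb that holds 157 others. Of 25 list members at 0 in both libraries, 17 lie inside another row.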

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

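Settings on histones, control abundance, overlap and GC content were chosen after the data were seen; the others were set before the data were examined. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The counts of 301 higher and 74 lower genes moved to 2933 and 1228 with no floor, 184 and 33 with a floor of 200, and 699 and 253 at 1.5-fold. Scaling to the same total gave 219 higher and 122 lower, and the larger activin-A share of the 30 abundant genes produces the shift of that scaling. Pseudocounts of 0 and 8, the trimmed mean of M-values and removal of the GC trend left the counts between 271 and 304 higher and between 67 and 76 lower. Protein-coding genes without histones gave 164 higher, leaving out control values of 2000 or more as well gave 123 higher, and rows free of overlap gave 220 higher and 48 lower. Unique symbols without Gm and Rik genes gave 203 higher and 67 lower. The genes entering numbered 21120 with no floor and 10379 with a floor of 200, in place of 12516. Their number alone does not account for these counts. With no floor the higher and lower genes rose by more than the genes entering, and with a floor of 200 they fell by more. The hypoxia and HIF1 median of 0.01 turned to −0.0095 with no floor (percentile 95.5, no longer set apart), −0.19 under scaling to the same total, −0.0096 with trimmed mean of M-values and −0.0016 once the GC trend was removed. Scaling to the same total also turned the medians of Th1 (−0.0099), cytokine receptors (−0.12) and amino acid response genes (−0.17), because it shifts every gene by −0.19. For that reason it also turned 3 lists that were not set apart, non-pathogenic Th17 (−0.0061), chemokines (−0.16) and stromal markers (−0.07), and took the ectonucleotidase median to 0.0024 and the Th17 core median to 0.09; a shift alters no percentile. Among lists not set apart, a floor of 200 turned non-pathogenic Th17 (−0.0072) and interferon-stimulated genes (0.06), and no floor turned chemokines (−0.03), interferon-stimulated genes (0.06) and innate-like T cell markers (0.17). B cell markers passed the lower limit with no floor (−0.17) and with a floor of 200 (−0.19), and had a median of −0.0018 among protein-coding genes alone; 11, 9 and 8 members entered these settings in place of 10, which moves the median by construction. Against random lists not matched on expression, hypoxia (0.0082), cytokine receptors (0.075) and amino acid response (0.0209) were no longer set apart, and glycolysis (−0.15) and ribosomal proteins (−0.14) became so. Setting the median ratio to 0 moved nothing, because it was already 0. Of 155 named genes, scaling to the same total changed the sign of 5, took 6 of 43 below 2-fold (Ahr, Il22, Il3, Il18rap, Klrd1 and Klrk1) and took 5 others past it (Ccr8, Egr2, Hspa1a, Hspa1b and Oas1a, all lower). Depth limits low genes most, and 3 reads correspond to a normalized count of 3.50 in control and 2.63 with activin-A.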

Other observations

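The genes in this paragraph were chosen after their values were seen. Several receptor genes of the natural killer cluster on chromosome 6 were higher in the activin-A library. Of 8 Klr genes past the floor, 6 were at least 2-fold higher, or 3 under scaling to the same total, and no enrichment was tested. Klre1 stood at 27 and 134, Klrc1 at 607 and 1510, Klrc2 at 92 and 271, and Klrc3 at 50 and 115; the Klrc genes are close copies and uncertain one by one. Klrg2, elsewhere on chromosome 6, was lower, at 90 and 63. Inha, which encodes the inhibin subunit that opposes activins, stood at 54 and 200, 3.65-fold higher (2.71 to 5.25). Procr, the protein C receptor gene, stood at 437 and 1592, 3.64-fold higher (3.26 to 4.08), and the ubiquitin-like gene Ubd at 105 and 495. On the lower side, Spp1, which encodes osteopontin, stood at 47935 and 17742, 2.70-fold lower (2.66 to 2.75). Epas1, which encodes the oxygen-regulated factor HIF-2α, stood at 670 and 274, 2.44-fold lower (2.13 to 2.82), where Hif1a was 1.13-fold lower. P2ry1, an ADP receptor gene, stood at 1504 and 741, 2.03-fold lower (1.86 to 2.21).

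The tests in the paragraphs that follow were chosen after the results were seen. Th2 genes, with Gata3, Il5 and Il13, were lower in the activin-A library. A wrong scaling would lower all genes by about as much, but the housekeeping median was −0.12, and the median ratios of GC bins of protein-coding genes spanned 0.08, far less than the Th2 median of −0.58, so neither scaling nor GC content accounts for the whole pattern. A difference between the cultures other than activin-A cannot be told apart from its effect with 1 library per group. The activin-A library also differed in RNA composition, with more small noncoding and histone RNA and a larger share in 30 abundant genes, and whether this goes with the Th2 values was not tested. Lower Th2 gene expression under activin-A is a hypothesis that further cultures could test.

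Small noncoding RNA took 0.0407% of the control total and 0.734% of the activin-A total, and the 60 rows past the floor had a median log2 ratio of 6.21. More RNA without a poly(A) tail in that library is a candidate explanation: the histone list fixed in advance, whose transcripts also lack the tail, had a median of 1.16. More cells in S phase would raise replication genes as well, and the cell cycle list had a median of −0.06 with an upper quartile of 0.04, which argues against it. A biological change in small RNA under activin-A was not tested.

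Besides Il17f, 30 abundant protein-coding genes were at least 4-fold higher, Lars2, Il31ra and Camk1d among them. An excess of reads of repeated sequence inside the gene bodies may be counted for these 30 genes. Neither read positions nor the mm9 sequence were analysed here, so this cannot be told apart from a higher expression of the 30 genes.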
